A study of Homo sapiens with 44 samples.

How the data were processed

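The data describe undifferentiated human induced pluripotent stem cells of the line WTC-11 (catalogue name GM25256), in which SUZ12 was normal (WT) or mutant (A2J2mut1, A2J2mut2 or PEmut). Of the 44 samples, 38 have a column in one of 3 count tables. 14 are RNA-seq libraries of clones, made from ribosomal-RNA-depleted RNA with a KAPA RNA HyperPrep kit, per the labels' protocols. 24 are ChIP-seq and input libraries of polyclonal lines, made with a KAPA HyperPlus kit. The remaining 6 samples are H3K27me3 ChIP libraries, 3 per genotype for WT and A2J2mut2. They have no column in the tables and were not analysed here.

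Each table deposited by the authors holds raw counts per gene and library, with replicates not pooled. Tools named per the submitters' processing notes are Trimmomatic 0.36, Bowtie2 2.2.9, Picard 2.6.0, bedtools 2.25.0, deepTools 3.0.1, featureCounts, DESeq2 1.26.0, HISAT2 2.1.0 and HTSeq 0.9.1, with the build hg38. The notes do not say which of the tools made which table. Column names mark duplicates as removed, per the file headers. The annotation release, the counter, its use of strand and its handling of reads over several genes are not given in the sources used here. In the input libraries, counts rose with the genomic length of genes (Spearman's rho 0.885 over 27224 genes; slope of the logs 0.652, so less than in proportion), so the ChIP counts appear to cover whole genes and not only promoters. The sources used here do not state this.

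The tables share 60609 genes, named by versioned Ensembl identifiers. The 45 second copies of genes shared by the sex chromosomes held 0 counts and were left out, which kept 60564. Of these, 60295 had an entry in the name table and 42005 a gene symbol, of which 1266 shared their symbol with another gene and keep their identifier here. Chromosomes and coordinates (40202 genes) come from a RefSeq table of assembly GRCh38.p14. Antisense and overlapping genes are uncertain, since the use of strand is not stated, and so are near-identical copies such as pseudogenes and immunoglobulin segments.

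RNA-seq libraries were summed per clone within each experiment, since the clone carries the genotype. This gave 10 values from 9 clones, 5 WT and 4 PEmut, with clone PEmut.2 in both experiments. In experiment 1 libraries of one clone differed less than clones of the same genotype did: the chi-squared statistic per degree of freedom was 2.24 to 2.53 within and 3.29 to 5.92 between WT clones, and 2.96 to 4.66 and 5.88 to 8.93 for PEmut. In experiment 2, with 1 library per clone and deeper libraries, it was 15.6 to 29.8 between clones. Genes were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests with TMM scaling, filtering by edgeR's expression filter and Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05. The fits were PEmut against WT over both experiments with experiment as a term, within each experiment, and the difference of the genotype effect between experiments. Levels are CPM, counts scaled to a common library total.

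ChIP libraries were fitted per antibody in edgeR, 8 libraries at a time, so that the 4 genotypes share one estimate of spread. The labels call the libraries of each genotype polyclonal and name no separate lines within it. The spread is therefore that between libraries, and ChIP p-values do not measure spread between lines of one genotype. Scaling factors were TMM factors over 18193 background genes, those at or below the median of mean log2 ChIP over input among 36385 genes with enough counts. Genes bound by PRC2 were defined over all 24 libraries as those with ChIP above input by at least 1.5-fold at an adjusted p under 0.05, with the 8 ChIP groups and the 4 input groups weighted equally; genes enriched at least 2-fold form the stronger part. Change over the bound set was tested with fry (limma 3.58.1), which tests whether its genes move one way on balance and does not compare them with other genes. Log2 levels used a prior count of 2. The 2 libraries of an antibody and genotype differed slightly beyond counting noise, with a chi-squared per degree of freedom of 1.15 to 1.53. The input pairs of WT (1.006) and A2J2mut1 (1.007) agree within sampling noise. Inputs of different lines ranged from close to this (1.013, WT replicate 1 against PEmut replicate 2) up to 1.54. Whether the input replicates, biological by the labels, are in part technical therefore cannot be told from this agreement. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333, so none was used, and the p-values given come from models fitted across all genes.

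Fixed lists of genes, 24 in all, were written before the data were examined, as were the main tests and the rule for naming genes. They are the PRC2 core, the PRC2.1 and PRC2.2 accessory subunits, PRC1 subunits, HOX clusters, primed and naive pluripotency, neuroectoderm, mesoderm, endoderm, trophoblast and amnion, neural crest, fibroblast and mesenchyme, developmental regulators of the GATA, TBX, LHX, NKX and 1 further kind (the GATA to NKX regulators), PAX and FOX regulators, WNT ligands and antagonists, BMP, TGF-beta and FGF ligands, cyclin-dependent kinase inhibitors, imprinted genes, p53 targets, the 20q11.21 region, cytosolic ribosomal proteins, housekeeping genes and mitochondrially encoded genes. Lists were tested with camera (limma) at a preset correlation of 0.01 and at an estimated correlation, with adjustment over lists. Called members were counted with adjustment over all genes and adjusted over the list alone. Named RNA genes are the PRC2 subunits, the 10 largest rises and up to 10 largest falls among called genes with a mean of at least 1 CPM, a gene symbol that is not a clone-based or LINC name and the same direction in both experiments, and up to 4 members per list with the smallest adjusted p. Named ChIP genes are the 5 largest rises and 5 largest falls among bound called genes and up to 4 members per list; for input they are the 3 genes with the smallest p. Some genes that these rules would name are not reported here. Genes named outside these rules were chosen after their values were seen and are marked so.

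Total counts per library were 10148561 to 17242178 in RNA experiment 1, 20145936 to 25159347 in experiment 2, 11137134 to 18704438 with the SUZ12 antibody, 11038358 to 17128576 with the Flag antibody and 7354119 to 10641622 in input. The fits were tested on simulated data with 200 changed genes per comparison, some raised and some lowered, with a mean of at least 1 CPM. Simulated ChIP counts were refitted without the background scaling, so that step was not tested. Simulated clone values were drawn independently, although clone PEmut.2 is in both experiments. The shares of false calls hold for these settings alone. The RNA fit over both experiments recovered 64.2% of 1.5-fold and 94.0% of 2-fold changes, with 3.39% of calls false. The SUZ12 fit recovered 52.2% and 85.1%, with 7.06% false, and the Flag fit 50.7% and 79.1%, with 1.94% false. RNA experiment 1 alone recovered 40.3% of 1.5-fold and 70.1% of 2-fold changes and experiment 2 alone 16.4% and 80.6%, with 6.71% and 8.39% of calls false.

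The alternatives tried were RLE and column-total scaling, no expression filter, DESeq2 1.42.0, single libraries in place of clone sums, a block by replicate number, the input change subtracted from the ChIP change, bound genes defined at 2-fold, from WT SUZ12 libraries alone, by column totals or as protein-coding genes alone, input pairs summed, PEmut.2 left out of experiment 2, and each library or clone left out in turn. XIST and Y-linked genes are not reported.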

Results

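The study asked how altered forms of SUZ12 change where Polycomb repressive complex 2 (PRC2) sits on chromatin and which genes are expressed, in human induced pluripotent stem cells of the line WTC-11. SUZ12 is a core subunit of PRC2, the enzyme that places the repressive histone mark H3K27me3, and the series title names the PRC2.1 and PRC2.2 subcomplexes as competitors. The labels do not expand the mutant names A2J2mut1, A2J2mut2 and PEmut. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on polyclonal lines of WT and the 3 mutants, with an antibody to SUZ12, with an antibody to the Flag peptide tag, and without antibody (input), with 2 libraries each. The labels do not state which protein carries the tag. No separate lines are named within a ChIP genotype, so an effect of genotype on ChIP cannot be told apart from a difference between lines. RNA-seq was done on clones. Experiment 1 had WT.1, WT.2, PEmut.1 and PEmut.2 with 2 libraries each, and experiment 2 had WT.5, WT.8, WT.10, PEmut.2, PEmut.4 and PEmut.10 with 1 library each. Total counts per library were 11137134 to 18704438 with the SUZ12 antibody, 11038358 to 17128576 with Flag, 7354119 to 10641622 for input, 10148561 to 17242178 in RNA experiment 1 and 20145936 to 25159347 in experiment 2. Changes are log2 of mutant over WT ± SE from edgeR, levels are CPM ± SD over 2 libraries for ChIP, and adjusted p is from edgeR's quasi-likelihood test.

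PRC2 signal lay over developmental regulators that pluripotent cells keep silent. All 16 measured genes of the HOX clusters, which pattern the body axis, were bound, as were 25 of 29 regulators of the GATA, TBX, LHX, NKX and 1 further kind (the GATA to NKX regulators) and 21 of 25 PAX and FOX regulators. Bound members also made up 18 of 24 neuroectoderm genes, 18 of 27 mesoderm genes, 10 of 18 endoderm genes, 9 of 17 trophoblast and amnion genes and 6 of 12 neural crest genes. Signalling genes followed with 10 of 27 WNT ligands and antagonists and 10 of 32 BMP, TGF-beta and FGF ligands. By this definition edgeR called 0 of 20 primed pluripotency, 0 of 37 cytosolic ribosomal protein and 0 of 14 housekeeping genes bound. It also called 0 of 15 fibroblast and mesenchyme genes and 0 of 20 genes of the 20q11.21 region bound. Lists of this size hold few bound genes at the share over all genes, and none of these passed Fisher's exact test. The adjusted p by that test was 0.761 for primed pluripotency and 20q11.21 and 0.279 for ribosomal protein genes. Over all genes, 2159 of 36385 were bound at least 1.5-fold over input and 699 at least 2-fold. The 1.5-fold set depends on the libraries used. WT SUZ12 and WT input libraries alone gave 2397 bound genes, of which 1154 were among the 2159. Of the 2159, 1093 were protein coding, 365 were pseudogenes, 130 were long non-coding RNA genes and 495 had no gene type in the annotation. Fisher's exact test against all other genes gave an adjusted p of 1.72e-19 for HOX clusters, 8.18e-26 for GATA to NKX regulators, 0.0652 for the cyclin-dependent kinase inhibitors (2 of 5 bound) and 0.215 for PRC1 subunits (3 of 20). Counts appear to cover whole genes, which would dilute a signal over the promoter of a long gene.

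With the SUZ12 antibody, A2J2mut1 libraries carried more signal than WT libraries over most strongly bound developmental genes. A higher ChIP yield of the A2J2 libraries was not tested. For either antibody it cannot be told apart here from more binding. HOXD3, a gene of the HOX clusters, rose by 1.66 ± 0.05, from 45.8 ± 5.23 to 144 ± 9.83 CPM (n = 2 each). The forebrain and eye regulator PAX6 rose by 1.48 ± 0.06 (40.9 ± 5.88 to 113 ± 12.7 CPM), and CBX8, a chromodomain subunit of PRC1, by 1.51 ± 0.08. Members of every germ layer were among the rises: EN1 (1.58), LHX2 (1.34) and OTX1 (1.65) of the neuroectoderm, HAND1 (1.65), NKX2-5 (1.65) and PAX2 (1.16) of the mesoderm, and PDX1 (1.73), SOX17 (1.60), GATA4 (1.38) and FOXA2 (1.46) of the endoderm. So were CDX2 (1.56) and TFAP2A (1.46) of the trophoblast list, MSX1 (1.65) of the neural crest, the signals WNT1 (1.39), GDF6 (1.46) and FGF5 (0.74), the cell cycle inhibitor CDKN2C (1.503) and the pluripotency factor KLF4 (1.17). The largest rises among bound genes included the antisense RNAs FOXD1-AS1 (2.38) and FOXC2-AS1 (2.253) and LINC01475 (2.04, chromosome 10, 99526350 to 99531177 in GRCh38.p14), and the largest falls included MIR4283-1 (−1.64) and BCAP31P2 (−1.55), a microRNA and a pseudogene. CPEB2, with as few as 3 counts in a library, read 2.50; its adjusted p was 0.0897 without A2J2mut1 replicate 2.

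By list in SUZ12 ChIP of A2J2mut1, 14 HOX genes rose, 0 fell and 2 did not pass. Of the GATA to NKX regulators 26 rose and 0 of 29 fell, of PAX and FOX regulators 22 rose and 0 of 25 fell (23 adjusted over the list alone), of neuroectoderm genes 22 rose and 2 did not pass. Mesoderm had 16 rises of 27 (18 adjusted over the list alone), endoderm 11 rises and 1 fall of 18, trophoblast 9 rises and 3 falls of 17, neural crest 7 rises of 12, WNT genes 12 rises of 27 (13 rises and 2 falls adjusted over the list alone), and BMP, TGF-beta and FGF ligands 15 rises and 2 falls of 32 (17 and 2 adjusted over the list alone). PRC1 subunits went both ways with 5 rises and 5 falls of 20, and 10 of 20 genes of the 20q11.21 region fell, such as HM13 (−0.38) and NOL4L (−0.29); the median of that list was −0.22, and that of the unbound genes of chromosome 20 as a whole −0.17. camera called 13 of 23 lists at the preset correlation and 11 at an estimated one. The 2 it lost were PRC1 subunits, with an adjusted p = 0.0767 with an estimated correlation, and 20q11.21, with an adjusted p = 0.358 with an estimated correlation. Over all genes edgeR called 2036 higher and 4431 lower of 36155. TMM over all genes gave 3490 higher and 2670 lower and RLE 3497 and 2666, so the balance of calls outside the bound set depends on scaling. Among genes bound at least 2-fold, 581 rose and 5 fell of 688, with a median of 1.12 and limma fry adjusted p = 0.000384 (over 10 ChIP comparisons); TMM over all genes gave 589 and 3, and with the input change subtracted 320 and 0 were called by edgeR. The A2J2 gain itself helps to place a gene in that set, since all ChIP libraries are averaged. Of 608 genes bound at least 2-fold in PEmut SUZ12 libraries, which lie outside the comparison, 387 (63.7%) rose and 11 fell, with a median of 1.07; such sets were chosen after the results were seen. The total of 6467 calls became 3397 without A2J2mut1 replicate 1 and 4098 without WT replicate 1.

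A2J2mut2 showed a further gain with the SUZ12 antibody. FOXC1, a regulator of eye and mesoderm development, rose by 2.99 ± 0.10, from 6.85 ± 0.0434 to 54.5 ± 4.09 CPM (n = 2 each), FOXD1 by 2.69 ± 0.15 and the homeobox gene LBX2 by 2.65 ± 0.14. GATA4, a heart and endoderm regulator, rose by 1.79 ± 0.03, from 136 ± 12.3 to 469 ± 16.0 CPM, and PAX6 by 2.01 ± 0.05, to 164 ± 6.65 CPM. CBX8 rose by 2.245 ± 0.07. Rises elsewhere were HOXD3 (1.88), HOXB7 (2.04) and HOXC4 (1.96) of the HOX clusters, OTX1 (2.13) and LHX2 (1.81) of the neuroectoderm, TBXT (1.71) and HAND1 (2.15) of the mesoderm, PDX1 (2.02) and SOX17 (2.19) of the endoderm, CDX2 (2.02), MSX1 (2.12) and MSX2 (2.14) of trophoblast and neural crest, and WNT1 (1.89), WNT10B (1.88), GDF6 (1.92) and INHBB (1.82) among signals. CDKN2C (1.92), CDKN1C (1.31), the imprinted gene PHLDA2 (1.58) and the PRC2.1 subunit gene EPOP (0.81) rose as well. Among bound genes 874 rose and 77 fell; the falls HLA-C (−2.37) and IGHD5OR15-5A (−1.88) rest on as few as 2 counts in a library, and the adjusted p of HLA-C was 0.124 without A2J2mut2 replicate 2 and that of IGHD5OR15-5A 0.232 without A2J2mut2 replicate 1. MIR4283-1 (−1.501) fell too, and SPARC (−0.64), an extracellular matrix gene outside the bound set, also fell.

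By list, 14 of 16 HOX genes rose in SUZ12 ChIP of A2J2mut2 (16 adjusted over the list alone), 26 of 29 GATA to NKX regulators, 21 of 25 PAX and FOX regulators (22 adjusted over the list alone), 21 of 24 neuroectoderm, 17 of 27 mesoderm, 10 of 18 endoderm (12 rises and 1 fall adjusted over the list alone), 10 of 17 trophoblast (with 1 fall) and 7 of 12 neural crest genes. Of WNT genes 14 of 27 rose and of BMP, TGF-beta and FGF ligands 14 of 32, with 1 fall. PRC1 subunits had 4 rises and 3 falls of 20, p53 targets 1 rise of 19, imprinted genes 4 rises of 18, and ribosomal protein genes 0 calls of 36. camera called 12 of 23 lists, and all 12 also at an estimated correlation. Over all genes edgeR called 1549 higher and 2008 lower of 36155, against 2273 and 1197 with TMM over all genes and 2275 and 1199 with RLE. Among genes bound at least 2-fold, 608 rose and 3 fell of 688, with a median of 1.53 and limma fry adjusted p = 0.000193. The rises were 457 with the input change subtracted (median 1.52). Of 608 bound at least 2-fold in PEmut SUZ12 libraries 393 (64.6%) rose and 6 fell, with a median of 1.51. The total of 3557 calls lay at 2048 without WT replicate 1, 2244 without WT replicate 2, 2158 without A2J2mut2 replicate 1 and 1847 without A2J2mut2 replicate 2.

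PEmut differed little from WT with the SUZ12 antibody. HOXD3 rose by 0.32 ± 0.06, from 45.8 ± 5.23 to 56.9 ± 0.727 CPM (n = 2 each); without WT replicate 1 its adjusted p was 0.212. NKX2-5, a heart regulator, fell to −0.40 ± 0.09 (adjusted p 0.00421), and lost its call without PEmut replicate 1 or WT replicate 2, with an adjusted p of up to 0.596. GATA4 (0.16), PAX9 (0.35), LHX9 (0.28), TFAP2B (0.24), GATA3 (0.27), HOXA2 (0.35) and CDKN2C (0.37) rose slightly; with the input change subtracted HOXA2 read −0.07 and 0 genes were called by edgeR in this comparison. The largest rises among bound genes were ENSG00000279064.1 (1.03), ENSG00000288187.1 (1.00), TSSC4 (0.82) and the neural regulator ATOH1 (0.65), and the largest falls BCAP31P2 (−1.07), COPDA1 (−0.93) and CDRT15P9 (−0.73). PAX6 (0.12, adjusted p 0.455) and CBX8 (0.08, adjusted p 0.7996) did not pass. All 21 called genes named by rule lost their call when at least 1 of the 4 WT and PEmut libraries was left out. HOX clusters had 2 rises of 16 (9 adjusted over the list alone), GATA to NKX regulators 4 rises and 1 fall of 29, trophoblast genes 2 rises of 17 (5 adjusted over the list alone) and neuroectoderm genes 0 calls of 24 by edgeR (3 rises and 1 fall adjusted over the list alone). camera called 7 of 23 lists at the preset correlation and 0 at an estimated one; for HOX clusters the adjusted p = 0.225 with an estimated correlation.

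Over all genes in that comparison edgeR called 76 higher and 401 lower of 36155, with 4677 genes at an unadjusted p under 0.05. TMM over all genes gave 255 higher and 179 lower, RLE 265 and 183, and column totals 138 and 269. Among 2140 bound genes 22 rose and 20 fell, against 33 and 13 with TMM over all genes or RLE. Among genes bound at least 2-fold 19 rose and 4 fell of 688, with a median of 0.01 (−0.10 without WT replicate 1, 0.13 without WT replicate 2) and limma fry adjusted p = 0.830. The total of 477 was 84 without PEmut replicate 1, 1449 without PEmut replicate 2, 95 without WT replicate 1 and 149 without WT replicate 2, and among bound genes the 42 calls were 12, 98, 20 and 41 in that order. When a library was left out of a pair, the lone sample of that group was assumed to vary like the other groups.

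With the Flag antibody, A2J2mut1 showed gains that were strongest at the HOX clusters. HOXB13, the most posterior gene of its cluster, rose by 1.73 ± 0.19, from 2.64 ± 0.0797 to 8.76 ± 0.562 CPM (n = 2 each), HOXA9 by 1.72 ± 0.22, HOXD3 by 1.32 ± 0.06 (44.5 ± 5.39 to 111 ± 10.8 CPM) and TLX1, a spleen and neuron regulator, by 1.71 ± 0.10. The RNA gene HOXC-AS3, antisense to HOXC genes, read 1.84 ± 0.18. HOXD10 (1.56), HOXB7 (1.55) and HOXC4 (1.37) rose too, with EN2 (1.38), DLX1 (1.04), EN1 (0.95) and PAX6 (0.79) of the neuroectoderm, NKX2-5 (1.11) and PAX2 (0.90) of the mesoderm and FOXA1 (1.33), PDX1 (1.16), GATA4 (0.95) and SOX17 (0.88) of the endoderm. CDX2 (1.04), WNT1 (1.03), GDF6 (1.06), CDKN2C (0.85) and CBX8 (1.02) rose as well, and so did LIN28A (0.50), an RNA-binding factor of pluripotent cells. FOXA2, a liver and gut regulator that rose with the SUZ12 antibody, read −0.10 here (adjusted p 0.697) and did not pass. Of bound genes 125 fell, and the largest falls included the pseudogenes MED15P1 (−1.48) and BCAP31P2 (−1.35). KLF4 (0.57) rose, but its adjusted p was up to 0.165 without A2J2mut1 replicate 1 or WT replicate 1; MIR132 (1.72) rests on as few as 5 counts, with an adjusted p of 0.475 without A2J2mut1 replicate 1. With the input change subtracted, KLF4 read −0.19 and MIR132 −0.03.

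By list in Flag ChIP of A2J2mut1, 15 of 16 HOX genes, 18 of 29 GATA to NKX regulators (19 adjusted over the list alone), 13 of 27 mesoderm, 7 of 12 neural crest and 7 of 17 trophoblast genes (9 adjusted over the list alone) rose, and 1 trophoblast gene fell. Neuroectoderm had 13 rises and 1 fall of 24, PAX and FOX regulators 16 and 2 of 25, endoderm 8 and 1 of 18, WNT genes 7 and 2 of 27, and BMP, TGF-beta and FGF ligands 5 and 1 of 32. In the 20q11.21 region 7 of 20 genes fell, with a list median of −0.24 against −0.15 for the unbound genes of chromosome 20 as a whole. camera called 14 of 23 lists, of which 5 held with an estimated correlation: HOX clusters, trophoblast, neural crest, neuroectoderm, and PAX and FOX regulators. Mesoderm and GATA to NKX regulators had an adjusted p = 0.0551 with an estimated correlation, endoderm 0.0592, WNT genes 0.065, BMP, TGF-beta and FGF ligands and kinase inhibitors 0.12, primed pluripotency 0.133, PRC1 subunits 0.146 and 20q11.21 0.198. edgeR called 1284 genes higher and 3108 lower of 36104, against 2449 and 1688 with TMM over all genes and 2398 and 1711 with RLE. Among genes bound at least 2-fold 435 rose and 8 fell of 690, with a median of 0.63 and limma fry adjusted p = 0.00492. Subtracting the input change left 113 rises (median 0.62). Of 606 bound at least 2-fold in PEmut SUZ12 libraries 315 (52.0%) rose and 16 fell, with a median of 0.52. Over all 2146 bound genes the median was 0.08 with limma fry adjusted p = 0.0230, and the unadjusted value, 0.0207 with all libraries, was 0.0932 without WT replicate 1, 0.0522 without WT replicate 2, and 0.0693 and 0.0840 without A2J2mut1 replicates 1 and 2. The total of 4392 was 1601 without A2J2mut1 replicate 1, 2185 without WT replicate 1 and 2758 without WT replicate 2; the 660 calls among bound genes were 436 without A2J2mut1 replicate 1.

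A2J2mut2 gave the largest gains of the 6 comparisons with WT, with the Flag antibody. FOXC1 rose by 3.5998 ± 0.10, from 5.63 ± 0.753 to 68.6 ± 5.79 CPM (n = 2 each), FOXD1 by 3.56 ± 0.14, TLX1 by 3.09 ± 0.08 (10.9 ± 0.245 to 92.9 ± 8.98 CPM), PAX6 by 2.48 ± 0.06 (37.3 ± 5.74 to 209 ± 20.7 CPM) and HOXD3 by 2.32 ± 0.06 (to 223 ± 23.4 CPM). PRC1 genes rose with CBX8 (2.71) and PCGF1 (1.90). HOXB7 (2.55) and HOXC12 (2.54) rose among HOX genes, DLX1 (2.73), EN1 (2.46) and LHX2 (2.17) in the neuroectoderm, TBXT (2.09) and HAND1 (2.61) in the mesoderm, SOX17 (2.62), PDX1 (2.45) and GATA4 (2.19) in the endoderm, CDX2 (2.49) and MSX1 (2.51) in trophoblast and neural crest, and WNT1 (2.34), GDF6 (2.29), CDKN2C (2.34), CDKN1C (1.20), KLF4 (1.54) and PHLDA2 (1.61) elsewhere. The fall that held in every left-out fit was IGHG2 (−1.23), an immunoglobulin gene, which read 0.83 with the input change subtracted. All 16 HOX genes rose, with 26 of 29 GATA to NKX regulators (27 adjusted over the list alone), 21 of 25 PAX and FOX regulators, 20 of 24 neuroectoderm, 17 of 27 mesoderm, 11 of 18 endoderm (1 fell), 8 of 17 trophoblast (1 fell), 7 of 12 neural crest, 14 of 27 WNT (1 fell) and 15 of 32 BMP, TGF-beta and FGF genes (1 fell). camera called 13 of 23 lists, and 11 at an estimated correlation; PRC1 subunits had an adjusted p = 0.0716 with an estimated correlation and 20q11.21 an adjusted p = 0.507 with an estimated correlation. edgeR called 1656 genes higher and 2571 lower of 36104, against 2395 and 1567 with TMM over all genes and 2525 and 1479 with RLE. Among genes bound at least 2-fold 599 rose and 1 fell of 690, with a median of 1.84 and limma fry adjusted p = 0.000193. Rises came to 514 with the input change subtracted (median 1.82). Of 606 bound at least 2-fold in PEmut SUZ12 libraries 382 (63.0%) rose and 10 fell, with a median of 1.79. The total of 4227 was 2403 without WT replicate 1, 2481 without A2J2mut2 replicate 1 and 2620 without A2J2mut2 replicate 2.

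In PEmut the Flag signal was lower than in WT over the same kinds of developmental genes. NKX2-5 fell to −2.53 ± 0.13, from 30.4 ± 7.06 to 5.29 ± 0.520 CPM (n = 2 each), BARX1, a regulator of stomach and jaw, to −2.36 ± 0.24, SKOR1, a spinal cord corepressor, to −2.23 ± 0.10 and the blood and gut regulator HLX to −2.43 ± 0.36. The PRC1 gene CBX8 (−1.24) fell. So did FOXD2 (−1.98), FOXQ1 (−1.59) and FOXF2 (−1.44) among forkhead genes, NKX2-3 (−1.85) and NKX3-2 (−1.48) among NKX genes, HOXD12 (−1.12), HOXC12 (−1.05) and HOXD3 (−0.68) among HOX genes, EN1 (−1.35), NKX6-1 (−1.05) and LHX2 (−0.87) in the neuroectoderm, FOXF1 (−1.38) and OSR1 (−1.09) in the mesoderm, PDX1 (−1.37), FOXA2 (−1.11), SOX17 (−0.93) and GATA4 (−0.58) in the endoderm, CDX2 (−0.95) and HAND1 (−0.81) in trophoblast and MSX1 (−1.11) in neural crest, and WNT1 (−1.62), WNT6 (−1.28), GDF6 (−0.99) and FGF3 (−1.06) among signals. PAX6, outside the rule here and looked up because it was named in the other comparisons, fell too (−0.64). NPAS4, an activity-induced neuronal factor, was the 1 bound gene that rose (0.58 ± 0.10, 13.3 ± 1.38 to 20.0 ± 1.58 CPM). ENSG00000283689.1 had 0 counts in a PEmut library, so no fold is given. GATA2 (−0.75) and MSX2 (−0.54) fell, with an adjusted p of 0.0773 and 0.3299 without WT replicate 2.

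By list, 10 of 16 HOX genes fell in Flag ChIP of PEmut (11 adjusted over the list alone) and 0 rose, with 20 of 29 GATA to NKX regulators (23 adjusted over the list alone), 18 of 25 PAX and FOX regulators (20), 10 of 27 mesoderm (12), 8 of 18 endoderm, 7 of 17 trophoblast and 4 of 12 neural crest genes. In the neuroectoderm 13 fell and 1 rose of 24, and 9 of 27 WNT genes (13 adjusted over the list alone), 5 of 32 BMP, TGF-beta and FGF ligands and 4 of 20 PRC1 subunits fell. Primed pluripotency, ribosomal protein and housekeeping genes had 0 calls by edgeR of 20, 34 and 14. camera called 11 of 23 lists lower at the preset correlation and 0 at an estimated one, where HOX clusters had an adjusted p = 0.0679 with an estimated correlation, and no list had a lower one. Over all genes edgeR called 183 higher and 1523 lower of 36104, against 557 and 834 with TMM over all genes, 694 and 757 with RLE and 420 and 1071 with column totals. Among genes bound at least 2-fold 1 rose and 358 fell of 690, with a median of −0.56 and limma fry adjusted p = 0.0103; TMM over all genes gave 2 and 336. Subtracting the input change left 93 falls (median −0.59). Of 1012 genes bound at least 2-fold in A2J2 SUZ12 libraries, outside the comparison, 1 rose and 396 (39.1%) fell, with a median of −0.39. The total of 1706 was 451 without PEmut replicate 1, 2488 without PEmut replicate 2, 650 without WT replicate 1 and 810 without WT replicate 2. The 474 calls among bound genes were 298 without PEmut replicate 1 and 312 without WT replicate 2.

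**Figure D1:**
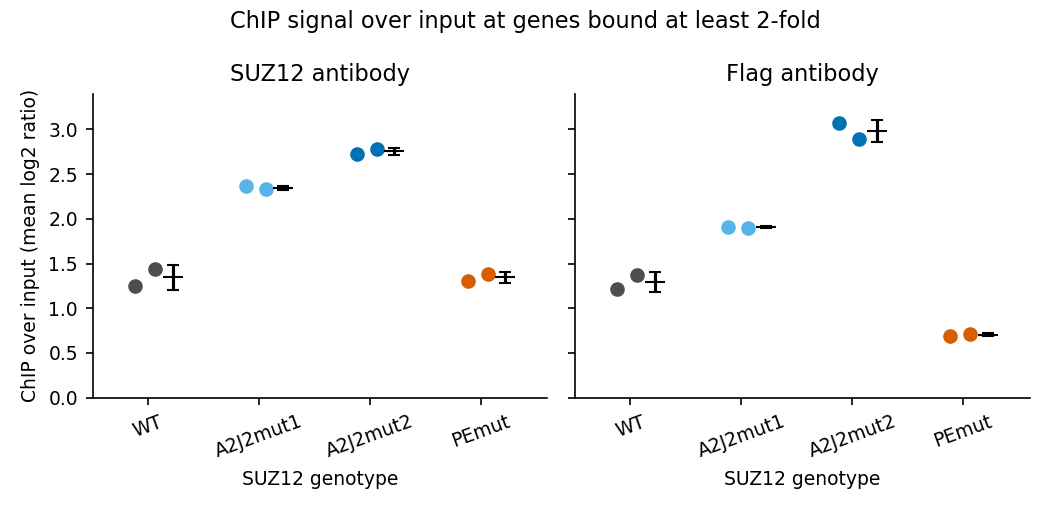
Mean log2 of ChIP over input across genes bound at least 2-fold, for each library (points) with the mean and SD of 2 libraries, by genotype and antibody. With the SUZ12 antibody WT stands at 1.34 and A2J2mut2 at 2.75; with Flag PEmut stands at 0.70.

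The signal averaged over genes bound at least 2-fold, a set that the A2J2 gain helps to fill, shows the same order per library. With the SUZ12 antibody the mean log2 of ChIP over input was 1.34 ± 0.14 in WT, 2.35 ± 0.02 in A2J2mut1, 2.75 ± 0.04 in A2J2mut2 and 1.34 ± 0.06 in PEmut (SD, n = 2). With Flag it was 1.29 ± 0.11, 1.91 ± 0.01, 2.98 ± 0.13 and 0.70 ± 0.02 in the same order. Genes enriched 1.5 to 2-fold had a median SUZ12 change of −0.11 in A2J2mut1 and −0.02 in A2J2mut2. Above 8-fold the medians were 1.60 and 2.03 with SUZ12 and 0.95 and 2.46 with Flag. Counts include background, which shrinks the log2 change of weakly enriched genes. The SUZ12 excess over input was therefore also read as a multiple of the WT excess, at 1.5 to 2, 2 to 4, 4 to 8 and above 8-fold. Its medians were 1.09, 2.62, 3.20 and 3.32 in A2J2mut1 and 1.24, 3.79, 4.64 and 4.62 in A2J2mut2. Enrichment was averaged over all genotypes, so a gain in the A2J2 mutants itself moves a gene to a higher group. With genes grouped instead by PEmut SUZ12 and PEmut input libraries, which enter neither side of these changes, the SUZ12 medians in A2J2mut1 and A2J2mut2 were −0.12 and −0.09 at 1.5 to 2-fold (1015 genes), 0.66 and 0.85 at 2 to 4-fold (458), 1.55 and 2.00 at 4 to 8-fold (119) and 1.58 and 1.96 above 8-fold (31). The Flag medians went from −0.15 and −0.13 at 1.5 to 2-fold to 0.94 and 2.42 at 4 to 8-fold. This grouping was chosen after the results were seen. In PEmut the Flag median went from −0.21 at 1.5 to 2-fold to −1.31 above 8-fold, and the SUZ12 median from −0.08 to 0.04. The median share of the WT excess that PEmut kept with Flag went from 0.66 to 0.29 between these groups. Over all genes bound at least 1.5-fold the SUZ12 medians were 0.13 in A2J2mut1 and 0.25 in A2J2mut2. They were 0.03 and 0.07 over genes bound in those PEmut libraries, and turned to −0.26 and −0.18 over the 2397 genes bound in WT SUZ12 libraries alone, a set picked on the same WT libraries that serve as the reference.

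**Figure D2:**
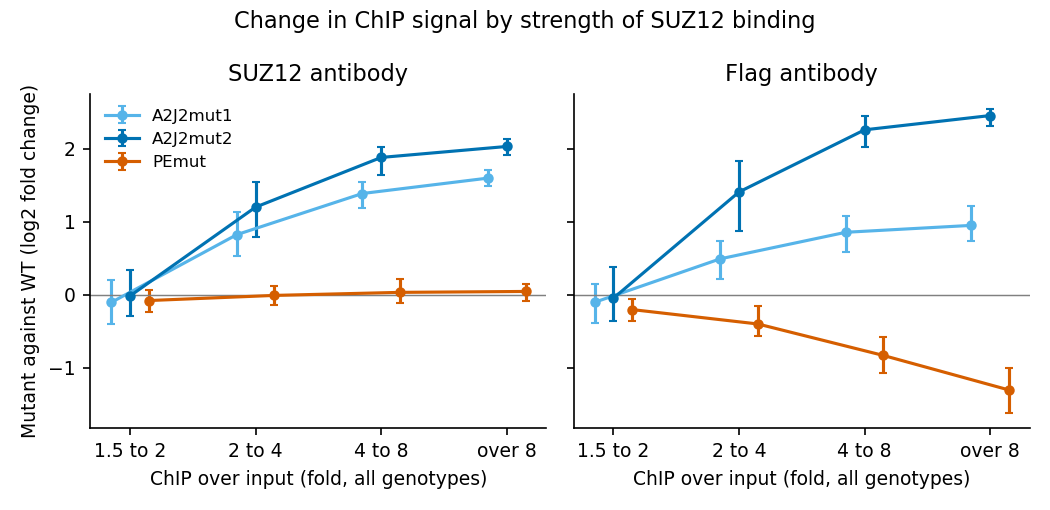
Median log2 change against WT of bound genes grouped by their enrichment over input, with the range from the lower to the upper quartile, for each mutant and antibody. Enrichment is averaged over all genotypes, the plotted mutants included, so the rise of the A2J2 medians is in part set by the grouping. Background counts also shrink the log2 change of weakly enriched genes. Above 8-fold enrichment the Flag medians are 0.95, 2.46 and −1.31 for A2J2mut1, A2J2mut2 and PEmut.

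The 2 A2J2 forms were compared directly, as were the 2 kinds of mutant. A2J2mut2 exceeded A2J2mut1 at 378 of 688 genes bound at least 2-fold with the SUZ12 antibody (2 lower, median 0.41, limma fry adjusted p = 0.00492) and at 544 of 690 with Flag (2 lower, median 1.10, limma fry adjusted p = 0.000632). By DESeq2 A2J2mut2 was higher at 211 of these genes with SUZ12 and 484 with Flag. Leaving out a library gave SUZ12 medians of 0.37 to 0.43. Over all genes edgeR called 640 higher and 35 lower with SUZ12, and 955 and 25 with Flag. The SUZ12 total of 675 was 368 and 400 without A2J2mut1 replicates 1 and 2, and 446 and 317 without A2J2mut2 replicates 1 and 2. PEmut lay below the mean of the A2J2 forms at 592 of 688 genes bound at least 2-fold with SUZ12 (1 higher, median −1.29, limma fry adjusted p = 0.000193) and at 606 of 690 with Flag (0 higher by edgeR, median −1.72, limma fry adjusted p = 0.000216). After subtraction of the input change, A2J2mut2 exceeded A2J2mut1 at 16 genes bound at least 2-fold with SUZ12 (median 0.45; over all bound genes limma fry no longer passed) and at 346 with Flag, and PEmut lay below the A2J2 mean at 451 and 519. Over sets bound at least 2-fold in SUZ12 libraries outside each comparison, A2J2mut2 was higher at 287 of 608 genes with SUZ12 and 372 of 606 with Flag, and PEmut was lower at 407 of 724 and 417 of 719. Over all genes the calls were 485 higher and 1169 lower with SUZ12 (810 and 1086 with column totals; 1094 in all without PEmut replicate 2) and 138 and 1233 with Flag (357 and 1162 with column totals).

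Whether the antibodies saw the same change was tested as an interaction over all 16 ChIP libraries. In PEmut the Flag change lay below the SUZ12 change at 229 bound genes and above it at 1 of 2159, with a median difference of −0.58 over genes bound at least 2-fold and limma fry adjusted p = 0.00935 (over 3 mutants; 0.0157 over all bound genes). In A2J2mut1 222 bound genes were lower and 5 higher with Flag (median −0.42 over genes bound at least 2-fold, limma fry adjusted p = 0.0219; over all bound genes the median was −0.15 and the limma fry adjusted p = 0.0552). Those 227 were 88 without Flag WT replicate 2, 100 without SUZ12 WT replicate 1 and 144 without SUZ12 A2J2mut1 replicate 1. In A2J2mut2 52 were higher and 0 lower by edgeR (median 0.31 over genes bound at least 2-fold, limma fry adjusted p = 0.0510, and 0.114 over all bound genes), and this count was 0 without SUZ12 WT replicate 2, Flag WT replicate 1 or Flag A2J2mut2 replicate 1, 14 and 32 without SUZ12 A2J2mut2 replicates 1 and 2, and 120 to 136 without SUZ12 WT replicate 1 (124), Flag WT replicate 2 (120) or Flag A2J2mut2 replicate 2 (136). Across 682 genes bound at least 2-fold the antibodies' changes correlated with r = 0.65 in A2J2mut1, 0.93 in A2J2mut2 and 0.19 in PEmut. Over genes outside the bound set r was 0.40, 0.33 and 0.17 in the same order. The PEmut value is close to the latter, and over genes bound at least 1.5-fold it was 0.04. The antibodies share no ChIP library, and genes are not independent replicates.

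Input libraries, which hold no antibody signal, differed between lines at some genes. In A2J2mut1 the long chromosome 7 genes DPP6 and PTPRN2 fell to −0.34 ± 0.03 and −0.31 ± 0.03. In A2J2mut2 PTPRD rose by 0.11 ± 0.01, RBFOX1 fell to −0.17 ± 0.01 and PTPRN2 to −0.31. In PEmut LRP1B (0.06), DLG2 (0.05) and SKA2 (0.53 ± 0.11) rose. edgeR called 563 genes higher and 301 lower of 34803 in A2J2mut1, 252 and 113 in A2J2mut2, and 7 and 5 in PEmut, with a median size of 0.197 among those of A2J2mut1. Of the called genes 34 differed over 2-fold in A2J2mut1 (up to 2.35 in log2), 9 in A2J2mut2 (up to 2.02) and 1 in PEmut (1.23). Leaving out a library gave 207 to 388 in A2J2mut1 (207 and 379 without A2J2mut1 replicates 1 and 2, 388 and 321 without WT replicates 1 and 2). For A2J2mut2 it gave 127 and 140 without its replicates, and 160 and 102 without those of WT. For PEmut it gave 0 and 21 without its replicates, and 0 and 2 without those of WT.

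In RNA, PEmut and WT clones had similar levels of PRC2 subunits. SUZ12 itself, read as a check of the labels, was 61.0 ± 5.39 to 62.5 ± 17.8 CPM from WT to PEmut in experiment 1 (SD, n = 2 clones each) and 85.8 ± 8.37 to 91.8 ± 6.45 in experiment 2 (n = 3), a change of 0.08 ± 0.10 (adjusted p 0.704). The labels do not say what the mutation changes, so a similar level of SUZ12 RNA neither bears out nor contradicts them. The catalytic subunit genes EZH2 (0.04) and EZH1 (−0.29, adjusted p 0.118), with EED (0.08), RBBP4 (0.09) and RBBP7 (0.06), did not pass. Of PRC2.1 genes, PHF1 (−0.12), MTF2 (−0.03), PHF19 (0.03), EPOP (0.15), LCOR (−0.01) and LCORL (0.03) did not pass. AEBP2 of PRC2.2 read −0.37 ± 0.08 (adjusted p 0.0507, 185 to 145 CPM in experiment 1) and JARID2 0.04; EZH1 and AEBP2 fell when adjusted over the list alone.

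Across both experiments PEmut clones expressed more of several developmental regulators and PRC1 genes than WT clones. PAX6 rose by 2.80 ± 0.34 (adjusted p 0.00292). IRX5, a homeobox gene of heart and retina, rose by 2.08 ± 0.19, from 1.14 ± 0.216 to 4.19 ± 1.17 CPM in experiment 1 (n = 2 clones each) and 0.903 ± 0.257 to 4.24 ± 0.344 in experiment 2 (n = 3). CBX8 rose by 2.34 ± 0.30 (0.843 ± 0.195 to 2.46 ± 0.692 CPM in experiment 1, 0.406 ± 0.219 to 3.30 ± 0.198 in experiment 2), and the PRC1 gene BMI1 by 1.83 ± 0.25. The blood regulator GATA2 (2.66 ± 0.48), the growth factor receptor gene PDGFRA (1.90 ± 0.24), the glutamate transporter gene SLC1A2 (1.88 ± 0.27), AGAP2 (1.93), C1QL4 (1.78) and FAM241A (1.77) rose. WNT3, a primitive streak ligand, rose by 1.18 ± 0.16, IRX3 by 1.63, FOXD1 by 0.76 and the naive pluripotency factor TFCP2L1 by 0.69. ZFHX3, a zinc finger homeobox factor, had the largest fall among genes that met the naming rule, −1.22 ± 0.08 (67.8 ± 6.88 to 26.97 ± 1.21 CPM in experiment 1, adjusted p 2.72e-05). IL3RA (−0.91), CFAP144 (−0.86), SLC9C1 (−0.74), the imprinted gene MAGEL2 (−0.71), SYT12 (−0.59), RFTN2 (−0.56), NPIPA1 (−0.40, of a multicopy family) and ST6GAL1 (−0.33) fell. PAX7, a muscle and neural crest regulator, read −2.65 ± 0.61 (adjusted p 0.0658), the forebrain gene OTX2 −1.09 (0.0605) and LHX1 2.02 (0.0710), and did not pass.

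**Figure D3:**
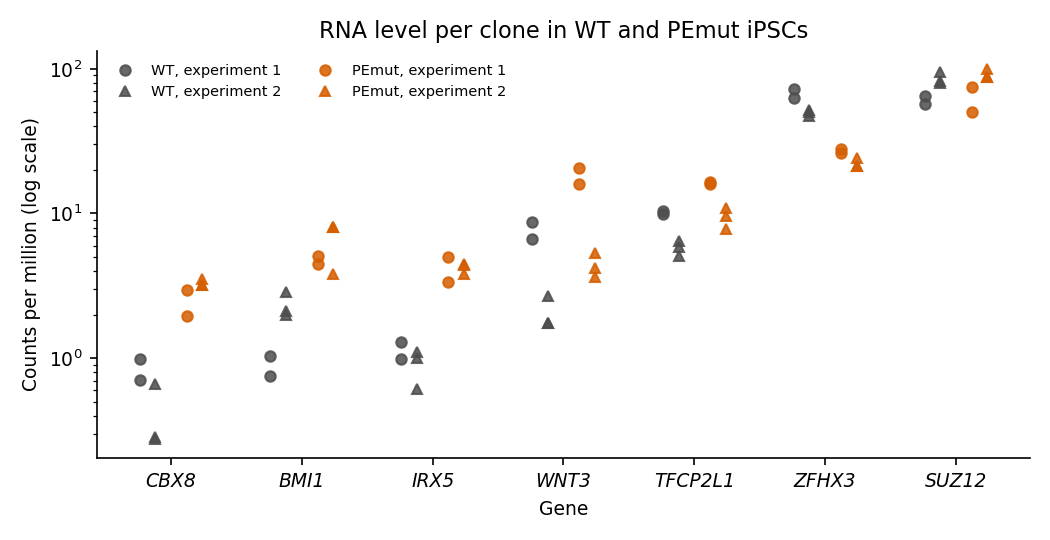
CPM of named genes in each clone by genotype and experiment, on a log axis, with 1 point per clone. CBX8 and IRX5 lie higher in PEmut clones and ZFHX3 lower in both experiments.

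edgeR called 131 genes higher and 19 lower of 19037 over both experiments, with 3660 at an unadjusted p under 0.05, 2030 of them higher. CBX8, IRX5, AGAP2, PDGFRA, C1QL4, ZFHX3 and PAX6 kept their call with any 1 clone left out. Without PEmut.2 the adjusted p was 0.0514 for SLC1A2, 0.0557 for BMI1, 0.0806 for FAM241A and 0.0557 for WNT3, and these 4 lost their call in no other left-out fit. Without PEmut.2 it was 0.0965 for FOXD1 and TFCP2L1, 0.144 for IRX3, 0.0967 for SLC9C1, 0.0822 for SYT12, 0.143 for MAGEL2 and 0.170 for NPIPA1 and ST6GAL1. Without WT.1 it was 0.116 for GATA2 and 0.113 for CFAP144, and without PEmut.4 0.125 for IL3RA and 0.126 for RFTN2. Each of the 12 genes from FOXD1 to RFTN2 lost its call in at least 2 left-out fits. The total of 150 was 41 without PEmut.2, 51 without WT.2, 53 without WT.1, 65 without PEmut.4, 97 without WT.10 and 309 without WT.5. In experiments 1 and 2 the called genes had medians of 0.94 and 0.85 for those that rose and −0.96 and −0.66 for those that fell; they were picked in the fit over both experiments, so their agreement in sign is no sign of replication.

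Among fixed lists, 3 of 21 PRC1 subunit genes rose in RNA and 0 fell (5 and 1 adjusted over the list alone), and PAX and FOX regulators had 2 rises of 12 measured (5 and 1), with a median of 0.30. Of the 7 endoderm genes measured 1 rose (4 and 1 adjusted over the list alone; median 0.90), of 13 neuroectoderm genes 2 (3 and 2), of 10 mesoderm genes 1 (4 and 0), of 7 trophoblast genes 1 (2 and 1), of 14 GATA to NKX regulators 1 (4 and 1), of 15 WNT genes 1 (1 and 1) and of 9 naive pluripotency genes 1 (3 and 1). Of 16 imprinted genes 1 fell. In 24 BMP, TGF-beta and FGF ligands 0 were called by edgeR over all genes (5 rises adjusted over the list alone), and the median was 0.27 with 19 values above 0. The lists with 0 calls by edgeR in both ways of adjustment were PRC2.1 subunits, 6 neural crest genes, 12 fibroblast and mesenchyme genes, 4 kinase inhibitors, 19 p53 targets, 20 genes of 20q11.21, 47 ribosomal protein, 14 housekeeping and 13 mitochondrially encoded genes. Primed pluripotency genes had 0 of 22 (2 rises adjusted over the list alone). HOXB13, the 1 HOX gene measured, read 0.08 (adjusted p 0.905). camera called endoderm, BMP, TGF-beta and FGF ligands and PAX and FOX regulators higher and p53 targets lower (median −0.19, with −0.56 within experiment 1 and 0.03 within experiment 2) at the preset correlation, and 0 lists at an estimated one. With an estimated correlation the adjusted p was 0.116 for endoderm and for PAX and FOX regulators, 0.214 for the ligands and 0.769 for p53 targets. For naive pluripotency the median of −0.23 and the direction of the test differ in sign, for imprinted genes the median of 0.01 and the test do, and for kinase inhibitors the median of 0.02 and the mean do; all 3 missed the threshold.

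Within experiment 1, edgeR called 461 genes higher and 244 lower of 19359 in PEmut, and within experiment 2 CBX8 and IRX5 higher and ZFHX3 lower of 19151 (adjusted p 0.0232 each). In experiment 1 the Nodal antagonist LEFTY1 rose by 4.23 and LHX1 by 4.61, and CDKN1A (−1.39) and GDF15 (−2.17), both p53 targets, fell; over both experiments these 4 did not pass. The difference of the genotype effect between experiments was called for 0 genes by edgeR (1186 at an unadjusted p under 0.05; 5 without WT.8) and 13 by DESeq2. The experiment 1 total of 705 was 7 without WT.2, 48 without WT.1, 1671 without PEmut.2 and 5505 without PEmut.1. The experiment 2 total of 3 was 0 without WT.10 or PEmut.4, 5 without WT.5, 7 without PEmut.2, 37 without WT.8 and 41 without PEmut.10.

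**Figure D4:**
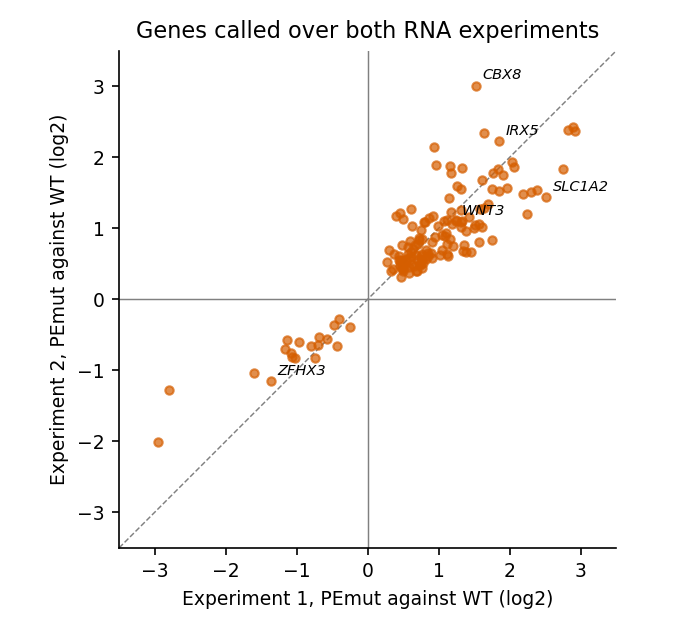
Log2 change of PEmut over WT in experiment 2 against that in experiment 1, for the genes called over both experiments, 1 point per gene. The genes were picked in the fit over both experiments, which favours points in the quadrants of equal sign.

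Genes bound by PRC2 were among the RNA rises more often than unbound genes. B4GALNT1, a ganglioside synthase gene, rose by 2.17 in RNA while its Flag signal in PEmut fell to −1.28; the kinase gene ITPKA read 2.03 and −1.19, the death-domain adaptor TRADD 2.00 and −1.23, BARX1 1.64 and −2.36, and TLX1 1.03 and −1.79. These 5 were chosen after their values were seen. B4GALNT1, ITPKA and TRADD rose more than some genes named for their size, and met the naming rule apart from its minimum of 1 CPM. Their RNA changes therefore rest on low levels. Among genes named by rule, IRX5 read 2.08 in RNA and −1.46 in Flag, and CBX8 2.34 and −1.24. Of 874 bound genes measured in RNA 36 rose and 0 fell by edgeR, against 95 rises and 19 falls among 18163 unbound genes, an odds ratio for rises of 8.17 (5.37 to 12.2, Fisher's exact p = 1.14e-18). Against 874 unbound genes matched on expression, of which 5 rose, the odds ratio was 7.46 (2.90 to 24.5, Fisher's exact p = 5.96e-07). Among 232 genes bound at least 2-fold 26 rose (11.207%). camera's p for the bound set was 0.00173 at the preset correlation and 0.337 with an estimated one, and for genes bound at least 2-fold 2.25e-16 and 0.00517. Of the 36 risen bound genes 23 (63.9%) were lower in Flag ChIP of PEmut, against 154 (18.5%) of 831 bound genes without an RNA call (odds ratio 7.75, Fisher's exact p = 7.61e-09). The risen genes were also more enriched, with a median log2 over input of 1.55 against 0.76, and Flag falls are more frequent among enriched genes. Within groups of enrichment the odds ratio was 3.17 (1.27 to 8.07, exact Mantel-Haenszel p = 0.00805, chosen after the results were seen): 2 of 10 risen genes fell at 1.5 to 2-fold against 65 of 627 without an RNA call, 9 of 13 against 59 of 165 at 2 to 4-fold, 9 of 10 against 24 of 33 at 4 to 8-fold and 3 of 3 against 6 of 6 above 8-fold. With the SUZ12 antibody 1 of the 36, SLC30A3 (−0.36), was lower; it was looked up because the count was 1. Across 230 genes bound at least 2-fold the RNA and Flag changes correlated with Pearson's r = −0.40 and Spearman's rho = −0.36, and RNA and SUZ12 changes with −0.13 and −0.09. Across the 867 bound at least 1.5-fold these were −0.32 and −0.14 with Flag and 0.04 and 0.05 with SUZ12; genes are not independent replicates, and RNA and ChIP came from different lines.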

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

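The tests of untagged SUZ12, of depth per clone and of the shifts by chromosome were chosen after the results were seen; the other tests were written before.

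The first pattern is the low Flag signal in PEmut beside a SUZ12 signal whose change did not pass. The interaction test found this difference at 230 bound genes. The labels do not state which protein carries the tag, so the tests of untagged SUZ12 assume that SUZ12 does. Untagged SUZ12 at one share in all mutant lines would put the SUZ12 change above the Flag change in each: over genes bound at least 2-fold the median of SUZ12 minus Flag change was 0.416 in A2J2mut1, which goes with it, and −0.306 in A2J2mut2, which does not, but there the limma fry adjusted p = 0.0510 missed the threshold, so this stays open. Untagged SUZ12 in the PEmut line alone stays open too, because the SUZ12 antibody kept a median share of 1.01 of the WT excess over input above 8-fold enrichment and the tables hold no untagged line. A lower yield of the 2 PEmut Flag libraries cannot be told apart from this. The kept share was 0.210 higher at 2 to 4-fold than above 8-fold, which the test as written beforehand reads against low yield. The relative departure of weak from strong genes, 0.706, lies within the 0.678 to 0.772 of the 4 A2J2 comparisons. That range was not part of the test as written. Yield was not tested in the A2J2 comparisons either, and the A2J2 gain itself moves genes between enrichment groups. The range therefore cannot settle whether the reading against low yield holds, and low yield stays open. No biological explanation was tested, since the design has no group that separates a loss of the PEmut protein from chromatin from these 3.

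The second pattern is that RNA experiment 1 called 705 genes and experiment 2 called 3. By the test as written, effects absent from experiment 2 are argued against. Of 698 genes called in experiment 1, 78.1% went the same way in experiment 2 without clone PEmut.2, against 60.8% of other genes. Genes are not independent replicates, and structure shared among few clones could raise such a share, so absence is not excluded. Changes of the called genes were smaller in experiment 2. The medians in experiments 1 and 2 were 0.806 and 0.298 for genes higher in experiment 1 and −0.687 and −0.205 for those lower. These genes were picked by their calls in experiment 1, which by itself makes their values in experiment 2 smaller. Lower depth is argued against, with a mean total per clone in experiment 2 of 0.890 times that of experiment 1. A larger spread between clones in experiment 2 fits its prediction, with a common dispersion 2.72 times that of experiment 1. Values of experiment 1 are sums of 2 libraries per clone, and those of experiment 2 are single libraries. The ratio therefore mixes spread between libraries with spread between clones and does not measure the latter alone. Only clone PEmut.2 was in both experiments, so what sets the spread stays open, and no biological explanation was tested.

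The third pattern is that ChIP signal of 32998 genes outside the bound set shifts by chromosome in every mutant, from −0.24 to 0.03 over 22 autosomes in SUZ12 ChIP of A2J2mut1 and from −0.07 to 0.06 in its input. The WT ChIP libraries alone are argued against, because the ChIP and input shifts over autosomes correlate with r = 0.983. Base composition of the fragments fits its prediction through a stand-in, coding genes per Mb, with a rho of −0.826; base content itself could not be read without a genome sequence. PRC2 binding outside the bound set, the biological explanation, would not shift input. The input shift, with r = 0.983 over autosomes, argues against it as the only cause. As a part of the cause it stays open, since the ChIP shift was wider than that of input. By its own test it stays open too, since r between ChIP and input change over single genes was 0.275.

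The number of calls was set against other splits of the clones. Over both experiments the real grouping called 150 genes and the highest other split 164, with WT.5 and PEmut.10 of experiment 2 swapped; of the 30 splits that keep the values of clone PEmut.2 in one group, 2, the real one included, called as many, so chance is not excluded at a share under 0.05. The other 30 splits, which part that clone, called at most 63 and were left out of the count after the results were seen. In experiment 2, 10 splits are too few for a share under 0.05; the real grouping called 3, and 2 of the splits, the real one included, called as many. The highest other, 127, puts PEmut.2 with WT.5 and WT.10, which points to a structure among the clones that was not tested further.

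The Flag change also differed from the SUZ12 change by the interaction test at 227 bound genes in A2J2mut1. In A2J2mut2 it differed at 52 bound genes.

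Single libraries stood far from the other 3 of their genotype in RNA experiment 1 for 6 of 34 group and measure pairs, and chance marks about 1 in 20 groups this way. In log2 CPM, WT.1 replicate 1 stood apart with EZH1 at 4.80 (others 4.94 to 4.97), EPOP at 4.45 (4.68 to 4.72) and AEBP2 at 7.64 (7.49 to 7.51). PEmut.1 replicate 1 stood apart with EZH1 at 4.70 (4.46 to 4.47), and PEmut.1 replicate 2 with EPOP at 4.35 (4.69 to 4.75). PEmut.2 replicate 2 had 17.2 M counts (others 12.2 to 12.6 M).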

How the results depend on the processing

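The input-pair sums, the fit without PEmut.2 in experiment 2, the DESeq2 test of the difference between experiments, protein-coding bound genes, genes bound in PEmut SUZ12 libraries or at least 2-fold in SUZ12 libraries outside the comparison, the Flag falls within groups of enrichment, and the left-out fits of that difference, of the bound set, of input and of the antibody difference were chosen after the results were seen; the other alternatives were planned, and all planned ones were run. Beyond left-out fits, 48 results had 279 alternatives: 225 kept their direction and side of the threshold (counts: stayed within 1.5 times), 45 moved, 6 reversed, 2 were weaker and 1 stronger. Counts by direction kept 260 of 388 alternatives (128 moved), named ChIP genes 3929 of 4307 (247 weaker, 72 stronger, 51 moved, 8 reversed), named RNA genes 490 of 602 (105 stronger, 5 moved, 2 weaker) and single lists 126 of 161 (35 weaker). Changes of 1.5-fold are often missed: simulated recovery was 40.3% in RNA experiment 1 and 16.4% in experiment 2 (70.1% and 80.6% at 2-fold), 50.7% with Flag, 49.3% in input, and 7.46% for the difference between experiments. Except where stated, the cause of a move was not tested.

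RNA calls went from 150 to 635 without the filter, 715 by DESeq2 (11.4% of its simulated calls were false), 2078 with single libraries (which count libraries of a clone as replicates) and 283 without PEmut.2 in experiment 2. Experiment 1 went from 705 to 2558 without the filter and 3696 with single libraries; experiment 2 from 3 to 110 without the filter and 90 by DESeq2. The difference between experiments, 0 by edgeR (1186 at an unadjusted p under 0.05), was 13 by DESeq2. With an estimated correlation camera called 0 lists (4 preset) in RNA, 0 (7) in SUZ12 PEmut, 5 (14) in Flag A2J2mut1 and 0 (11) in Flag PEmut, and the RNA test of bound genes gave a camera p of 0.337 (0.00173).

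By DESeq2, SUZ12 calls were 2800 (6467 by edgeR) in A2J2mut1, 1363 (3557) in A2J2mut2, 41 (477) in PEmut with 1 (42) bound, 259 (675) for A2J2mut2 against A2J2mut1 and 909 (1654) for PEmut against the A2J2 mean. Flag calls were 1668 (4392) with 408 (660) bound, 1743 (4227), and 453 (1706) with 294 (474) bound. With the input change subtracted, SUZ12 calls were 570 with 391 (906) bound in A2J2mut1, 752 with 585 (951) bound in A2J2mut2, 0 by edgeR and 0 bound in PEmut, 20 for A2J2mut2 against A2J2mut1 (bound median 0.22, fry no longer past the threshold) and 747 for PEmut against the A2J2 mean. Flag calls were 198 with 141 bound, 974, 119 with 98 bound, and 535 (980) for A2J2mut2 against A2J2mut1. Genes that reversed were PHLDA3 (−0.11), TM9SF4 (0.0396) and XKR7 (0.0246) in SUZ12 A2J2mut2, HOXA2 (−0.0708) in SUZ12 PEmut, MIR132 (−0.0311), KLF4 (−0.19) and PHLDA3 (−0.19) in Flag A2J2mut1 and IGHG2 (0.83) in Flag A2J2mut2. Input pairs summed gave 242 (365) calls in A2J2mut2 and 0 (12) in PEmut by edgeR. Bound genes were 699 at 2-fold. Over genes bound in WT SUZ12 libraries alone, a set picked on the WT reference, median changes were −0.26, −0.18 and −0.17 with SUZ12 in A2J2mut1, A2J2mut2 and PEmut (the last stronger), 0.0213 for PEmut against the A2J2 mean, and −0.17 and −0.14 with Flag in A2J2mut1 and A2J2mut2. Over genes bound in PEmut SUZ12 libraries the Flag A2J2mut1 median was −0.0117 (0.08 over all bound genes). SUZ12 PEmut at 2-fold had a median of 0.00773 (−0.05 at 1.5-fold).

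Left-out fits, lowest to highest, gave RNA calls of 41 to 309, 7 to 5505 in experiment 1, 0 to 41 in experiment 2 and 0 to 5 for the difference, with the lone sample of a group assumed to vary like other groups. Of 200 such fits 126 kept the result, 70 moved it and 4, all for the bound median of Flag A2J2mut1, were weaker. SUZ12 gave 3397 to 4589 in A2J2mut1 (bound 735 to 816, median 0.12 to 0.18), 1847 to 2244 in A2J2mut2 (803 to 861, 0.25 to 0.29), 84 to 1449 in PEmut (12 to 98, −0.12 to −0.00335), 317 to 446 for A2J2mut2 against A2J2mut1 (0.22 to 0.24) and 1094 to 2309 for PEmut against the A2J2 mean (−0.36 to −0.22). Flag gave 1601 to 3456 (436 to 579, 0.0513 to 0.12), 2403 to 2829 (879 to 946, 0.27 to 0.31), 451 to 2488 (298 to 458, −0.35 to −0.26), 789 to 929 (0.30 to 0.39) and 1135 to 1463 (−0.47 to −0.36) in the same order. Bound genes were 2089 to 2480, input calls 207 to 388, 102 to 160 and 0 to 21, and antibody differences 88 to 240, 0 to 136 and 157 to 251 (A2J2mut1, A2J2mut2, PEmut).

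The replicate numbers showed no clear pairing. Deviations of libraries from their group mean were correlated between groups. In RNA experiment 2 same-numbered clones gave 0.0550 to 0.232 and other pairs −0.298 to 0.225. There 3 of 6 correlated best with their own number, which does not settle a pairing. Same-numbered libraries of different clones in experiment 1 gave −0.145 to 0.0837, as deviations from clone means. Same-numbered ChIP libraries of different genotypes gave −0.0331 to 0.0827 with SUZ12 and −0.0727 to 0.161 with Flag. Deviations of 2 libraries mirror each other, so other pairs there repeat these values with the opposite sign. With a replicate block, RNA calls were 2092 over both experiments, 3077 in experiment 1 and 23 in experiment 2 (single libraries), and ChIP counts stayed within 1.5 times.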

Other observations

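Several bound genes that rose in RNA of PEmut have not been described above, and were picked after their values were seen (5 WT and 4 PEmut clones; 2 libraries per ChIP group). The liver and neural regulator ONECUT2 rose by 1.41 ± 0.22 in RNA and fell to −0.47 ± 0.06 with Flag, the homeobox gene LBX2 read 1.29 ± 0.17 and −1.22 ± 0.26, the transcription factor NFIC 1.12 ± 0.13 and −0.40 ± 0.05, the lymphoid regulator IRF4 1.16 ± 0.23 and −0.52 ± 0.10, the cell death gene HRK 0.99 ± 0.20 and −0.41 ± 0.10, and PRRT4 1.66 ± 0.20 and −0.73 ± 0.13. Other bound genes rose in RNA while their Flag value did not pass: GATA2-AS1, antisense to GATA2 (2.71 ± 0.35; Flag −0.36, adjusted p 0.252), the limb and neuron regulator LMX1B (1.59 ± 0.27; Flag −0.14, adjusted p 0.227), the cerebellin CBLN1 (1.53 ± 0.18; Flag −0.89, adjusted p 0.0610), DLX3 of skin and placenta (1.19 ± 0.19; Flag −0.66, adjusted p 0.0773), the neuronal splicing factor NOVA2 (0.92 ± 0.15; Flag −0.17, adjusted p 0.265), the receptor gene CNTFR (0.72 ± 0.10; Flag −0.01, adjusted p 0.970) and the neurofilament gene INA (0.68 ± 0.12; Flag −0.07, adjusted p 0.837). Of the 36 risen bound genes 23 fell with Flag and 0 rose by edgeR.

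In a principal component analysis of the 10 clone values, the first component (42.2% of variance) placed experiment 1 at −51.1 to −30.7 and experiment 2 at 12.03 to 40.0. On the second (18.2%), PEmut clones stood at −6.38 and −30.6 in experiment 1 and −10.6, −33.9 and −5.67 in experiment 2, and WT clones at 23.7 and 28.4, and 0.06, 25.7 and 9.31. The 2 genes with most RNA counts, ENSG00000280441.3 and ENSG00000278996.1, took 5.53% to 10.1% of the counts of a library, and mitochondrially encoded genes 1.49% to 2.46%. H3K27me3 libraries of WT and A2J2mut2 have no column in the tables, so this mark is not described.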
